A study of Mus musculus with 21 samples.

How the data were processed

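The 21 samples are total RNA of mouse femur, extracted with the miRNeasy kit, labelled with Cy3 and hybridized singly to Agilent mouse miRNA arrays, per the labels. Each sample was placed in its group, intact femur or fracture callus of day 1, 3, 5, 7, 11 or 14, from its title and characteristics. The deposited scanner files hold spot intensity values made by Agilent Feature Extraction, background-subtracted and spatially detrended but not normalized between arrays, per the file headers. They also hold flags for spots well above background, outlier spots and saturated spots, and the software's summed intensity per miRNA, per the file headers. A further table gives the authors' own intensity per miRNA on a linear scale for 922 miRNAs; its columns share 1 distribution and keep the rank order of the software's sum on each array (lowest Spearman correlation 1.00), so it holds that sum after quantile normalization. It lists the miRNAs that the software detected on at least 1 array, as checked on the files, and it was used as an alternative. The files name mm9 as the design's build; no matching annotation was used here, and no coordinates are given.

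From the 56430 non-control spots of each array, outlier spots were left out and the processed signal was divided by the array's 75th percentile over the 653 probes well above background on all 21 arrays. Between 18.0% and 35.0% of probes were well above background on an array, which is why the percentile rests on detected probes. Values below a common floor of 0.0400 of that percentile were set to the floor, then log2 was taken and the spots of a probe averaged. The floor is the highest, over the arrays, of the lowest scaled signal among probes well above background. Groups at the floor have no measured order, and their differences are understated. They also have no spread, which lowers the SE of the fit, so p-values of miRNAs with groups at the floor may be too small. Each miRNA, measured by 1 to 4 of 4415 probes, was represented by its brightest probe, and the 663 miRNAs well above background (over 50% of spots) on all 3 arrays of at least 1 group were tested. Probes of a miRNA were called in opposite directions only for miR-8105 (days 3, 5, 7 and 11) and miR-674-5p (days 7 and 11). No spot was saturated.

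Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided), in 1 fit of 7 group means, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05; every adjusted p of a miRNA comes from this fit. Where a miRNA was not well above background on any array of the dimmer group, its fold is a lower bound: the bright group's mean against the mean, over the dim group's arrays, of the higher of the array's lowest signal well above background and the probe's own signal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Replicate arrays correlated at 0.944 or more over the tested miRNAs.

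The rule for naming miRNAs was fixed before the data were examined, as were the lists and the first set of settings to vary. For each day against intact bone it takes the 10 largest rises and the 10 largest falls that passed and whose arrays do not overlap between groups, for each step between days the 3 largest of each, for the F-test the 10 smallest p, and for each list its members, with those of smallest adjusted p as the main examples. Over all 663 tested miRNAs, 534 on day 7 and 342 on day 1 had no overlap with intact bone, where chance gives 10% for 3 arrays against 3.

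The 19 fixed lists were skeletal muscle, erythroid, myeloid and neutrophil, lymphocyte, inflammation-induced, endothelial, chondrocyte, mesenchymal and fibroblast, osteoblast and matrix, osteogenesis-restraining, osteoclast, Dlk1-Dio3 locus, miR-17 family clusters, let-7 family, miR-30 family, cell cycle arrest and hypoxia, adipose and fatty marrow, epithelial, and nerve and liver miRNAs. A tested miRNA belongs to at most 1 of them, and most members are also expressed outside the cell type in the list's name. Lists with at least 3 tested members were tested with limma's camera, with the correlation between members estimated from the residuals, against all other tested miRNAs and with adjustment over the lists of a day.

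The slide of each array is given in the file headers. Slide 1 held 8 arrays, all of days 1 and 3 and day 5 replicates 1 and 2. Slide 2 held 7, intact bone, day 7 and day 5 replicate 3, and slide 3 held 6, days 11 and 14. Slide was therefore used as a fixed block for comparisons that day 5 links, and as a random block for all (estimated correlation −0.0668). The labels number replicates 1 to 3 in each group without naming a shared animal. Deviations from the group means of arrays with the same number correlated at 0.247 to 0.489 between day 1 and intact bone, 0.283 to 0.700 between days 3 and 1 and 0.168 to 0.535 between days 5 and 3; in the other comparisons at least 1 of the 3 correlations was under 0.1. Any pairing is therefore inferred from the data alone, and day 1 and intact bone lie on different slides.

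The fit and the set test were tested on simulated data before use. For a simulated day 7 against intact bone over 663 miRNAs, with 200 changed in each of 20 runs, 52.9% of changes of 0.5 on the log2 scale, 84.9% of changes of 1 and 99.3% of changes of 2 were recovered, with 3.81% false calls. A list moved by 1, the let-7 family, was called in 20 of 20 runs, and 0 of 360 tests of other lists passed. The simulated noise was independent between miRNAs, whereas the estimated correlation between let-7 family members in the data was 0.554. These runs therefore do not show how often camera would call a list of correlated members. The simulated noise also had the same spread in every group, no floor and no difference between slides. In the data the SD of miR-5128 was 0.00686 in intact bone and 1.33 on day 5. The shares recovered and the 3.81% false calls therefore hold for the simulated data and need not hold for the real arrays.

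Settings varied were quantile normalization, the percentile over all probes, the median of detected probes, normexp background correction with an offset of 50 followed by quantile normalization, the software's sum per miRNA, the mean over probes, and the authors' table with a pseudocount of 1. Others were no filter, only miRNAs above background on all arrays, the replicate number or the slide as a block, fits of 2 groups alone, an intensity trend with robust variances, a 2-fold limit, and each array left out in turn. For lists they were the preset correlation of 0.01, fry and the brighter arm of each hairpin. Normexp was planned on mean signals and was run on the median spot and background signals that the files used here give. Settings added after seeing the data were no scaling, scaling on the labelling spike-in, a lower floor, the arrays of 1 slide alone, and leaving out miRNAs numbered 1000 or higher. Low intensity limits the measurement below the floor, so miRNAs at the floor in every group were not tested.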

Results

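MicroRNA (miRNA) levels were measured in the healing femur of male C57BL/6 mice, on 21 Agilent mouse miRNA arrays with 1 array per sample. The series holds 7 groups of 3 samples. The control was the intact contralateral femur, and the other groups were fracture callus, the repair tissue that forms around a broken bone, on days 1, 3, 5, 7, 11 and 14 after fracture. The labels call the 3 members of a group separate samples without naming the animals, so p-values measure only the spread between these samples, and the number of arrays limits the precision. Each SE and p rests on 1 spread per miRNA, pooled over the 7 groups, and not on the 2 groups compared alone. Spreads were unequal: the SD of miR-6392-3p was 1.30 on day 3 and 0.0305 in intact bone. Where a group spreads more than the others, the SE can be too small for it. Differences below are log2 of callus over intact bone, or of the later over the earlier day, ± the standard error (SE) of the limma fit, with n = 3 arrays per group throughout. The miRNAs given with a fold or a log2 difference as the largest rises and falls of a comparison had no overlap between the 3 arrays of either group, which the naming rule requires.

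The scanner software detected 749 ± 40.6 miRNAs (mean ± SD, n = 3) in intact bone, a mean of 793 on day 1 and 535 ± 57.5 on day 7. The 75th percentile of the signal of the probes that were well above background on every array was 685 ± 91.5 intensity units in intact bone, 807 ± 343 on day 1, 312 ± 73.7 on day 7, 309 ± 32.7 on day 11 and 415 ± 79.6 on day 14. The arrays were scaled on this value, so every rise or fall below is relative to the array's other bright probes. Each labelling used 100 ng of total RNA, per the labels' protocols.

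**Figure D1:**
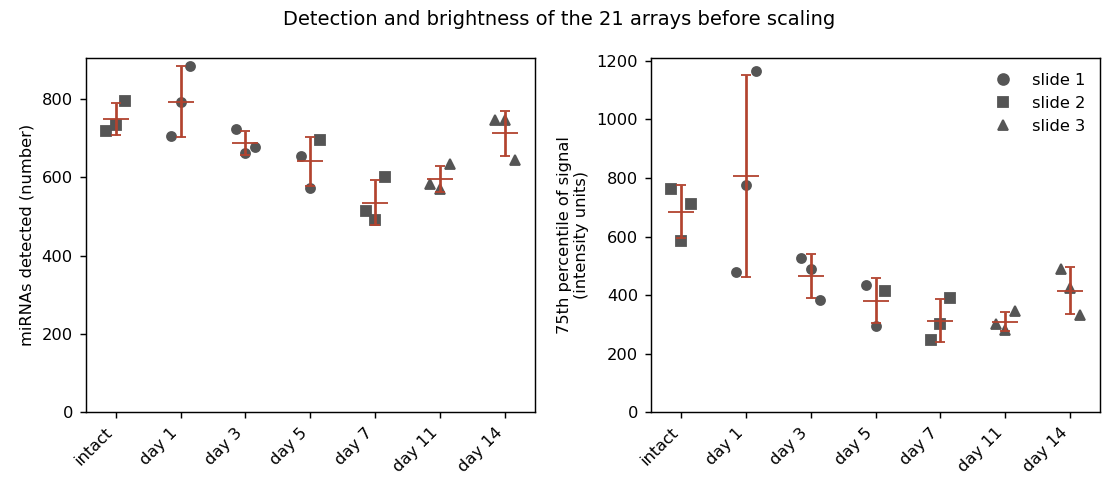
Number of miRNAs detected (left) and 75th percentile of the signal before scaling, in intensity units (right), for the 21 arrays by group. Marker shapes give the slide, red bars the mean ± SD of 3 arrays, and day 7 has the lowest mean number detected, 535.

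Over the whole course 499 of 663 tested miRNAs differed among the 7 groups in limma's F-test. Of these, 251 had their highest mean in intact bone, 113 on day 7 and 64 on day 11, and 258 had their lowest mean on day 7. The 10 with the smallest p were miR-6958-5p, miR-7038-5p, miR-5136, miR-3077-5p, miR-3572-5p, miR-666-5p, miR-3093-3p, miR-7046-5p, miR-6964-5p and miR-8091, each highest in intact bone. Their ranges were unequal. On the log2 scale miR-3572-5p spanned 2.52 (adjusted p = 6.22e-07), while miR-6958-5p (adjusted p = 4.07e-11) spanned 0.62. On no day 7 array was miR-6958-5p well above background, so its range is limited by the floor. The same held for miR-7038-5p and miR-6964-5p. Arrays at the floor have no spread, so the p-values of such miRNAs may be too small and their rank here too high.

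The same 100 miRNAs passed the test in the same direction on all 6 days, 48 higher and 52 lower than in intact bone. Those higher throughout included miR-335-5p, encoded within the Mest gene, whose differences ran from 1.60 to 4.67, the muscle miRNA miR-206-3p (1.37 to 2.70) and miR-378a-3p, encoded within Ppargc1b (1.40 to 1.77). Those lower throughout included miR-1187 (decreased by 1.31 to 2.97) and miR-574-5p (decreased by 1.22 to 2.90). Of the 52 lower ones, 45 had at least 1 group with all arrays at the floor, where p-values may be too small. At least 2-fold lower on every day were 4 of the 52, and at least 2-fold higher 17 of the 48 higher ones. The 6 comparisons share the intact arrays, and independent lists of these sizes would share 0.185. Unchanged groups simulated against shared controls gave a mean of 0 such miRNAs. With nothing changed, few miRNAs are called on any day, so this 0 could hardly differ and is no baseline for the 100. The controls are too few to split, so part of the excess over independent lists may come from the shared intact arrays. Without scaling 5 miRNAs passed on all 6 days and with spike-in scaling 8, and the number was 59 without intact replicate 3 and 62 without day 1 replicate 2. Of the 347 miRNAs above background on all arrays, 51 were higher and 6 lower on all 6 days. Here and below, that filter leaves out miRNAs that fell below background on any array or rose from it, so it bears on the split itself. With slide as a block 48 miRNAs passed on day 1 and 56 on day 3, so the 100 do not hold in that fit. There miR-335-5p, miR-1187 and miR-574-5p did not pass on days 1 and 3, nor miR-206-3p on day 3.

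**Figure D2:**
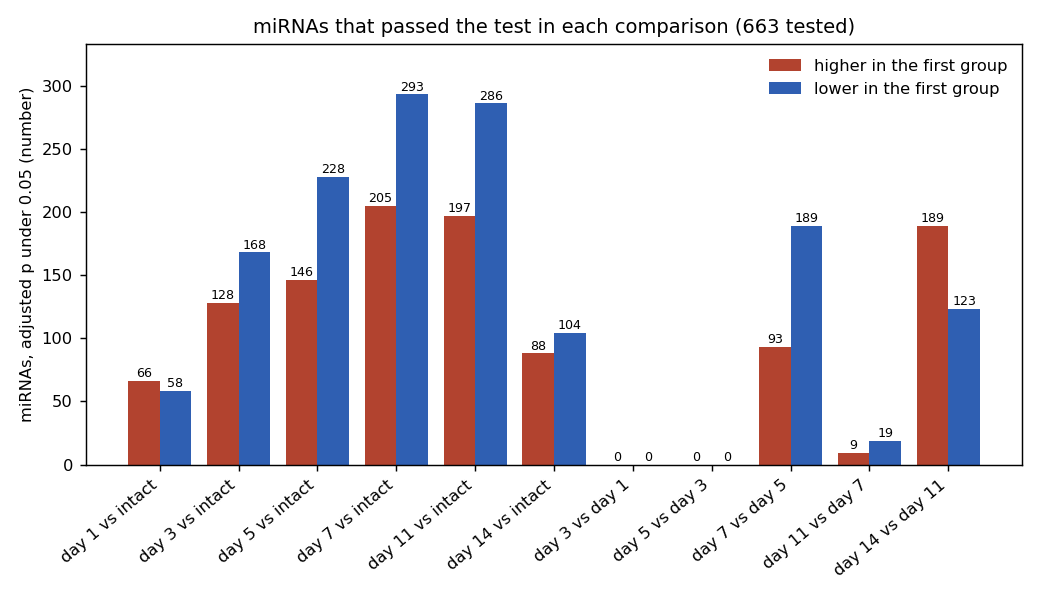
Number of the 663 tested miRNAs with an adjusted p under 0.05 in each comparison, higher (red) or lower (blue) in the group named first. Day 7 against intact bone has 205 higher and 293 lower, and day 3 against day 1 and day 5 against day 3 have 0.

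On day 1 after fracture, 124 of 663 miRNAs differed from intact bone, 66 higher and 58 lower. Most of the largest rises came from the imprinted Dlk1-Dio3 locus. They were led by miR-434-3p (4.14-fold, 2.05 ± 0.36, adjusted p = 0.000688), miR-337-3p (3.83-fold, 1.94 ± 0.32) and miR-299b-5p (1.91 ± 0.40). From the same locus rose miR-329-3p (1.89 ± 0.35), miR-127-3p (3.63-fold, 1.86 ± 0.28), miR-136-5p (1.80 ± 0.56), miR-300-3p (1.80 ± 0.32) and miR-154-5p (1.65 ± 0.27). The other 2 were miR-133a-5p (3.28-fold, 1.71 ± 0.29), abundant in skeletal and cardiac muscle, and miR-335-5p (1.60 ± 0.45). The largest falls were miR-1187, which fell by 1.48 (SE 0.36), miR-574-5p by 1.22 (SE 0.32), both on the log2 scale, miR-466i-5p (−1.16 ± 0.34) and miR-669n (−1.10 ± 0.29). Smaller falls were those of miR-7089-5p (−0.85), miR-666-5p (−0.81), miR-1247-3p (−0.78), miR-345-3p (−0.72), miR-468-3p (−0.67) and miR-6955-5p (−0.66).

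Among the fixed lists on day 1, 15 of 41 Dlk1-Dio3 locus miRNAs rose and 1, miR-666-5p, fell (16 and 1 adjusted over the list alone; median 0.37). Of the 7 skeletal muscle miRNAs 5 rose (5 adjusted over the list alone; median 1.38), among them miR-133a-3p (1.53 ± 0.33), miR-1a-3p (1.38 ± 0.42) and miR-206-3p (1.37 ± 0.34). Of the 10 members of the miR-30 family 8 rose (8 adjusted over the list alone; median 0.78), with miR-30a-3p at 1.23 ± 0.29, and of the 6 adipose and fatty marrow miRNAs 3 rose (5 adjusted over the list alone; median 0.82), all of them miR-378 forms. Rises were also called among the mesenchymal and fibroblast miRNAs (3 of 9; 3 adjusted over the list alone) and the endothelial miRNAs (2 of 4; 3 adjusted over the list alone), such as the endothelial-enriched miR-126a-3p (0.97 ± 0.23). The osteogenesis-restraining miRNAs held 4 rises among 15 (7 adjusted over the list alone) and the osteoblast and matrix miRNAs 2 among 11 (3 adjusted over the list alone). Among the nerve and liver miRNAs 1 of 4 rose (2 adjusted over the list alone), and among the inflammation-induced miRNAs 1 of 7 (2 adjusted over the list alone), where miR-155-5p, induced in activated immune cells, rose by 0.69 ± 0.17. The chondrocyte miRNAs held 2 rises and 2 falls among 11 (2 and 3 adjusted over the list alone), and the let-7 family 1 and 1 among 11 (4 and 1 adjusted over the list alone). The cell cycle arrest and hypoxia miRNAs held 1 fall among 8, miR-195a-3p (1 adjusted over the list alone). No member passed among the erythroid, myeloid and neutrophil, lymphocyte, osteoclast, miR-17 family and epithelial lists, also adjusted over the list alone.

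With camera at an estimated correlation no list passed on day 1: the smallest adjusted p was 0.387, for the miR-30 family, the skeletal muscle miRNAs, the endothelial miRNAs and the adipose and fatty marrow miRNAs. The split of calls moved with the scaling, to 43 higher and 74 lower by the median of detected probes, 61 and 2 without scaling, 79 and 7 with spike-in scaling and 82 and 25 in the authors' deposited table. It was 60 and 8 among the 347 miRNAs above background on all arrays, and 37 and 4 at a 2-fold limit. Day 1 and intact arrays lay on different slides, joined only through day 5, which has 1 array on the slide of intact bone. With slide as a block 48 miRNAs passed, 6 of the 10 largest rises and 2 of the 10 largest falls among them. In that fit 6 of 41 Dlk1-Dio3 locus miRNAs rose (median 0.63), 4 of 7 skeletal muscle miRNAs (median 2.17) and 4 of 10 miR-30 members (median 1.27). Rises in that fit also numbered 3 of 6 adipose and fatty marrow miRNAs (median 1.08), 1 of 9 mesenchymal and fibroblast miRNAs (median 0.15), 0 of 4 endothelial miRNAs (median 1.06) and 0 of 15 osteogenesis-restraining miRNAs (median 0.58). The chondrocyte miRNAs then held 1 rise and 1 fall (median −0.53), and 1 of 11 osteoblast and matrix miRNAs rose (median 0.68). In that fit the slide offset is set by day 5 replicates 1 and 2 against replicate 3. For miR-140-5p replicate 2 stood apart, at 1.65 against −0.70 and −0.76 in replicates 1 and 3. That array therefore enters the day 1 values with slide as a block, and its part in them cannot be told from the slide. No inflammation-induced miRNA passed (median 0.36), miR-155-5p included, and no cell cycle arrest and hypoxia miRNA (median −0.09), miR-195a-3p included, while the let-7 family held 0 rises and 1 fall (median 0.40). The count was 72 without day 1 replicate 2 and 76 without intact replicate 3. Of the 10 largest falls 8, among them miR-1187, miR-574-5p, miR-466i-5p and miR-669n, did not pass without at least 1 array, and 9 did not pass without scaling. Of the rises miR-136-5p and miR-335-5p did not pass without at least 1 array.

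**Figure D3:**
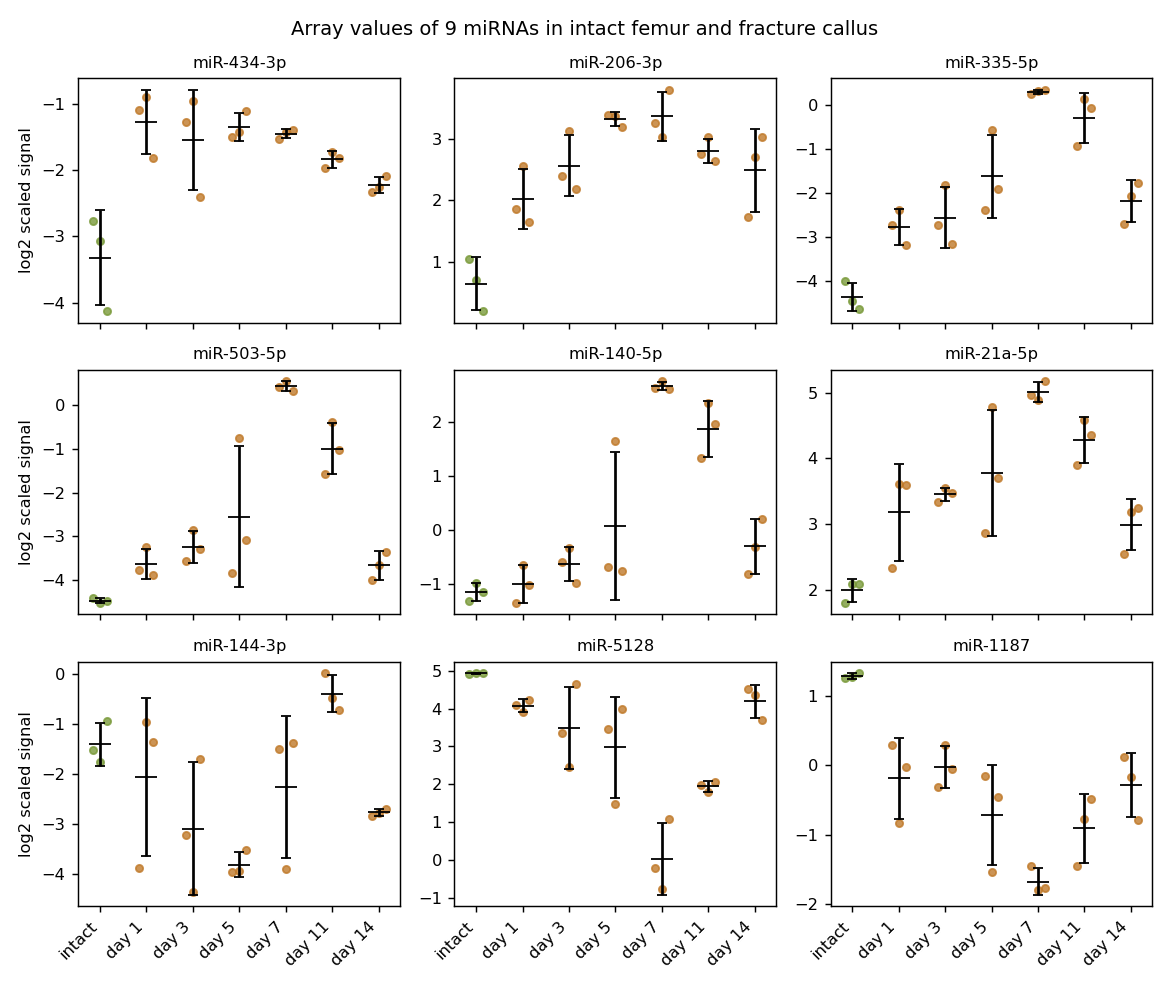
Scaled log2 signal of 9 miRNAs on each array in intact femur (green) and fracture callus (orange) by day, with the mean ± SD of 3 arrays. miR-140-5p and miR-503-5p are highest on day 7, while miR-5128 and miR-1187 are highest in intact bone.

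On day 3, 296 miRNAs differed from intact bone, 128 higher and 168 lower. The largest rise was that of miR-206-3p, a skeletal muscle miRNA (3.75-fold, 1.91 ± 0.34, adjusted p = 0.000733). Next came the Dlk1-Dio3 members miR-127-3p (3.66-fold, 1.87 ± 0.28), miR-379-5p (1.87 ± 0.30), miR-300-3p (1.82 ± 0.32). Also high were miR-434-3p (1.78 ± 0.36), miR-329-3p (1.69 ± 0.35), miR-299b-5p (1.69 ± 0.40) and miR-337-3p (1.66 ± 0.32) of the same locus. The other rises were miR-335-5p (1.80 ± 0.45) and miR-378d (1.63 ± 0.22). The largest falls were miR-714 (−1.84 ± 0.45), miR-144-5p (−1.78 ± 0.43), which belongs to an erythroid cluster driven by GATA1, and miR-6392-3p (−1.72 ± 0.61). Then came miR-1945 (−1.55 ± 0.32), miR-1187 (−1.31), miR-574-5p (−1.30), miR-8100 (−1.30), miR-7235-5p (−1.29), miR-1931 (−1.28) and miR-3470a (−1.27).

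Among the mesenchymal and fibroblast miRNAs 7 of 9 rose on day 3 (8 adjusted over the list alone; median 1.01), with miR-214-3p at 1.50 ± 0.40, miR-145a-5p at 1.21 ± 0.18 and miR-199a-5p at 1.10 ± 0.30. Both miR-199a and miR-214 are made from 1 transcript active in skeletal development. Of the osteogenesis-restraining miRNAs 9 of 15 rose (9, with 1 fall, adjusted over the list alone; median 0.69), led by miR-24-3p (1.19 ± 0.17), and 6 of 11 let-7 members rose and 1 fell (6 and 1 adjusted over the list alone; median 0.63). The lymphocyte miRNAs held 5 rises and 1 fall among 8 (5 and 1 adjusted over the list alone; median 0.46). The rises were miR-342-3p (0.65 ± 0.13) and 4 miR-181 forms, which many tissues express. Of miR-150, the 3p arm miR-150-3p fell (−0.95 ± 0.26), while miR-150-5p, abundant in mature lymphocytes, was at 0.46 ± 0.38 and did not pass. In the erythroid miRNAs 2 of 6 fell (1 adjusted over the list alone; median −0.40), miR-144-5p and miR-451a (−1.08 ± 0.41). In the myeloid and neutrophil miRNAs 1 of 4 fell (1 adjusted over the list alone; median −0.85), miR-1957a (−0.97 ± 0.27), and the neutrophil-abundant miR-223-3p, at −0.73 ± 0.42, did not pass. No list passed camera with an estimated correlation, the smallest adjusted p being 0.370.

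The day 3 split was 29 higher and 277 lower without scaling, which shifted the median of the miRNAs tested both ways by −0.50. Shifts for the other days are likewise over the miRNAs tested both with the setting and as reported. It turned to 129 and 62 among the 347 miRNAs above background on all arrays, 59 and 40 at a 2-fold limit, and 54 and 34 when only the arrays of these 2 groups were fitted. With slide as a block 56 miRNAs passed, 31 higher and 25 lower, 4 of the 10 largest rises and 0 of the 10 largest falls among them. Rises then numbered 1 of 9 in the mesenchymal and fibroblast miRNAs (median 0.64), 1 of 15 in the osteogenesis-restraining miRNAs (median 0.72). They numbered 0 of 11 in the let-7 family (median 0.63) and 0 of 8 in the lymphocyte miRNAs (median 0.64), with 0 falls in the erythroid miRNAs (median −0.31) and 0 in the myeloid and neutrophil miRNAs (median −0.20). As on day 1, the slide offset behind these values includes day 5 replicate 2. The count was 162 without day 3 replicate 2, 193 without intact replicate 1 and 190 without intact replicate 3. The falls of miR-1931, miR-6392-3p, miR-7235-5p and miR-8100 did not pass without at least 1 array, and that of miR-714 was −1.21 without day 3 replicate 2.

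On day 5, 374 miRNAs differed from intact bone, 146 higher and 228 lower. Leading the rises were miR-335-5p (6.71-fold, 2.75 ± 0.45, adjusted p = 0.000204) and miR-206-3p (6.30-fold, 2.66 ± 0.34). They were followed by miR-379-5p (4.64-fold, 2.21 ± 0.30) and miR-214-3p (4.48-fold, 2.16 ± 0.40). Further rises were miR-300-3p (2.11 ± 0.32), miR-127-3p (2.09 ± 0.28), miR-299b-5p (2.02 ± 0.40), miR-434-3p (1.98 ± 0.36), miR-337-3p (1.91 ± 0.32) and miR-503-5p (1.91 ± 0.55), a cell cycle-restraining member of the miR-16 seed group. Falling most were miR-144-3p (−2.40 ± 0.78), of the erythroid cluster, miR-1187 (−2.01 ± 0.36), miR-5128 (−1.95 ± 0.61), and miR-3082-5p (−1.86 ± 0.40). Next were miR-574-5p (−1.82), miR-144-5p (−1.75), miR-1945 (−1.67), miR-466i-5p (−1.64), miR-3473e (−1.60) and miR-3473f (−1.56).

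Of the mesenchymal and fibroblast miRNAs 8 of 9 rose on day 5 (9 adjusted over the list alone; median 1.36). Of the chondrocyte miRNAs 6 of 11 rose and 3 fell (6 and 4 adjusted over the list alone; median 1.05), with the cartilage miRNAs miR-455-3p at 1.90 ± 0.50, understated as its intact arrays lay at the floor, and miR-140-3p at 1.42 ± 0.43. Day 5 replicate 2 stood apart for miR-140-5p, at 1.65 against −0.70 and −0.76 in replicates 1 and 3. Its intact arrays were at −1.31, −0.99 and −1.15. The list was not counted without replicate 2, so how far this array carries its rises is open. Of the let-7 family 9 of 11 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.96), of the adipose and fatty marrow miRNAs 6 of 6 rose (6 adjusted over the list alone; median 1.09) and of the skeletal muscle miRNAs 5 of 7 (5 adjusted over the list alone; median 1.46). The erythroid miRNAs held 3 falls among 6 (3 adjusted over the list alone; median −0.51) and the myeloid and neutrophil miRNAs 2 among 4 (3 adjusted over the list alone; median −0.97), including miR-142a-3p (−1.46 ± 0.53), which blood cells of most lineages express. No list passed camera with an estimated correlation, the smallest adjusted p being 0.365.

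The day 5 split was 34 higher and 352 lower without scaling, with a shift of −0.71 in the median of the miRNAs tested both ways, and 101 and 286 with spike-in scaling. It turned to 134 and 94 among the 347 miRNAs above background on all arrays, and to 90 and 55 at a 2-fold limit. With slide as a block 146 miRNAs passed, 90 higher and 56 lower, among them 8 of the 10 largest rises and 2 of the 10 largest falls. The lists then held 4 rises of 9 for the mesenchymal and fibroblast miRNAs (median 1.26), 2 rises and 1 fall of 11 for the chondrocyte miRNAs (median 0.39). They held 6 rises and 1 fall of 11 for the let-7 family (median 1.04), and 2 rises and 0 falls of 6 for the erythroid miRNAs (median −0.52). Rises numbered 4 of 6 adipose and fatty marrow miRNAs (median 1.26) and 5 of 7 skeletal muscle miRNAs (median 1.96), and falls 0 of 4 myeloid and neutrophil miRNAs (median −0.49). In this fit the comparison rests on the 1 day 5 array on the slide of intact bone. Without day 5 replicate 2 the count was 228. The fall of miR-144-3p did not pass without day 5 replicate 2 or without intact replicate 3, and miR-5128 not without day 5 replicate 2. Without that array the rise of miR-503-5p was 1.01 and that of miR-214-3p 1.55. Neither passed with slide as a block, and miR-503-5p did not pass without scaling.

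Day 7 showed the most differences from intact bone, 498 of 663, 205 higher and 293 lower. Leading the day 7 rises were miR-503-5p (29.7-fold, 4.89 ± 0.55, adjusted p = 1.82e-06) and miR-335-5p (25.5-fold, 4.67 ± 0.45), both close to the floor in intact bone. They were followed by the cartilage miRNAs miR-455-3p (at least 16.3-fold, as all intact arrays lay at the floor), miR-140-5p (14.1-fold, 3.82 ± 0.49) and miR-140-3p (11.4-fold, 3.52 ± 0.43). The other arm of miR-455, miR-455-5p, was at least 17.9-fold higher (adjusted p = 6.12e-06) and not well above background in intact bone. The others were miR-214-3p (10.3-fold, 3.36 ± 0.40), miR-210-3p (9.07-fold, 3.18 ± 0.36), which hypoxia induces, miR-379-5p (8.71-fold, 3.12 ± 0.30) and miR-21a-5p (8.13-fold, 3.02 ± 0.40), which injury and inflammation induce. The largest falls were miR-5128 (−4.90 ± 0.61, 29.9-fold), miR-714 (−4.10 ± 0.45, 17.1-fold), miR-6392-3p (−3.90 ± 0.61), and miR-3473e (−3.69 ± 0.43). Then followed miR-1931 (−3.65 ± 0.44, well above background on 2 of 3 day 7 arrays) and miR-3472 (−3.43). The others were miR-7211-3p (−3.42), miR-6418-5p (−3.42), miR-6961-5p (−3.40, well above background on 1 of 3 day 7 arrays) and miR-8100 (−3.36). Of the 293 falls 236 carried numbers of 1000 or higher, against 16 of the 205 rises. In 143 of the 498 changed miRNAs 1 of the groups had all arrays at the floor.

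Of the mesenchymal and fibroblast miRNAs 8 of 9 rose on day 7 (8 adjusted over the list alone; median 2.61), including miR-199a-5p (2.83 ± 0.30). Of the chondrocyte miRNAs 7 of 11 rose and 4 fell (7 and 4 adjusted over the list alone; median 1.70). The rises were both arms of miR-140 and of miR-455, miR-675-3p, processed from the H19 RNA (at least 9.20-fold, adjusted p = 4.67e-06), miR-193b-3p (1.70 ± 0.22) and miR-365-3p (1.65 ± 0.29). The falls were miR-1247-3p (at least 3.47-fold lower), miR-193b-5p (at least 2.62-fold lower), miR-365-1-5p (−1.69 ± 0.20, limited by the floor on day 7) and miR-365-2-5p. Of the osteoclast miRNAs 4 of 5 rose (4 adjusted over the list alone; median 2.53), miR-503-5p, miR-148a-3p (2.53 ± 0.34), miR-34a-5p (2.21 ± 0.26) and miR-31-5p (at least 14.0-fold), none of them specific to osteoclasts. Of the Dlk1-Dio3 locus miRNAs 30 of 41 rose and 5 fell (32 and 6 adjusted over the list alone; median 1.23), and of the let-7 family 10 of 11 rose and 1 fell (10 and 1 adjusted over the list alone; median 1.51). The osteogenesis-restraining miRNAs held 10 rises and 2 falls among 15 (10 and 2 adjusted over the list alone; median 1.38), with miR-24-3p at 2.01 ± 0.17. The osteoblast and matrix miRNAs held 8 rises and 1 fall among 11 (8 and 1 adjusted over the list alone; median 0.97), with miR-196a-5p at 1.99 ± 0.29 and miR-29a-3p, which targets collagen transcripts, at 0.97 ± 0.19. The fall was miR-3960 (−3.03 ± 0.37).

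Other lists on day 7 held 5 rises of 7 among the inflammation-induced miRNAs (5 adjusted over the list alone; median 1.09, and −0.06 without scaling), 3 of 4 among the endothelial miRNAs (4 adjusted over the list alone; median 1.19) and 6 of 6 among the adipose and fatty marrow miRNAs (6 adjusted over the list alone; median 1.10, and −0.05 without scaling). The skeletal muscle miRNAs held 4 rises of 7 (1 adjusted over the list alone), with a median of 0.75 that was −0.38 without scaling and −0.14 with spike-in scaling. Within the list miR-206-3p stood at 2.70 ± 0.34 and miR-133a-3p at 0.76 ± 0.33. The miR-30 family held 6 rises and 1 fall among 10 (6 and 1 adjusted over the list alone), its median of 0.80 being −0.33 without scaling and −0.08 with spike-in scaling. The miR-17 family clusters, which promote proliferation, held 5 rises among 13 (2 adjusted over the list alone), with a median of 0.47 that was −0.68 without scaling and −0.43 with spike-in scaling. The lymphocyte miRNAs held 5 rises and 1 fall among 8 (5 and 1 adjusted over the list alone; median 0.65, −0.50 without scaling and −0.25 with spike-in scaling). The cell cycle arrest and hypoxia miRNAs held 5 rises and 1 fall among 8 (5 and 1 adjusted over the list alone; median 0.54, −0.59 without scaling and −0.35 with spike-in scaling). The nerve and liver miRNAs held 2 rises among 4 (2 adjusted over the list alone; median 0.68, −0.47 without scaling and −0.22 with spike-in scaling). The erythroid miRNAs held 2 falls among 6 (2 adjusted over the list alone; median −0.72), the myeloid and neutrophil miRNAs 1 fall among 4 (1 adjusted over the list alone; median −0.68), and the epithelial miRNAs 0 calls among 3 in limma (0 adjusted over the list alone). No list passed camera with an estimated correlation, the smallest adjusted p being 0.299.

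Each of the 10 largest rises and 10 largest falls of day 7 passed in every scaling tried, without each array in turn and with slide as a block. The day 7 split was 256 higher and 203 lower by the 75th percentile over all probes, and 247 and 216 by the median of detected probes. Each came with a shift of 0.13 in the median of the miRNAs tested both with that setting and as reported. Among the 347 miRNAs above background on all arrays it was 156 and 141. It was 76 and 389 without scaling (shift −0.87), and 106 and 366 with spike-in scaling (shift −0.62). All arrays of day 7 and intact bone shared a slide, and 498 miRNAs passed on that slide alone. As these are the same arrays, neither that count nor the slide block is a separate check of day 7.

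**Figure D4:**
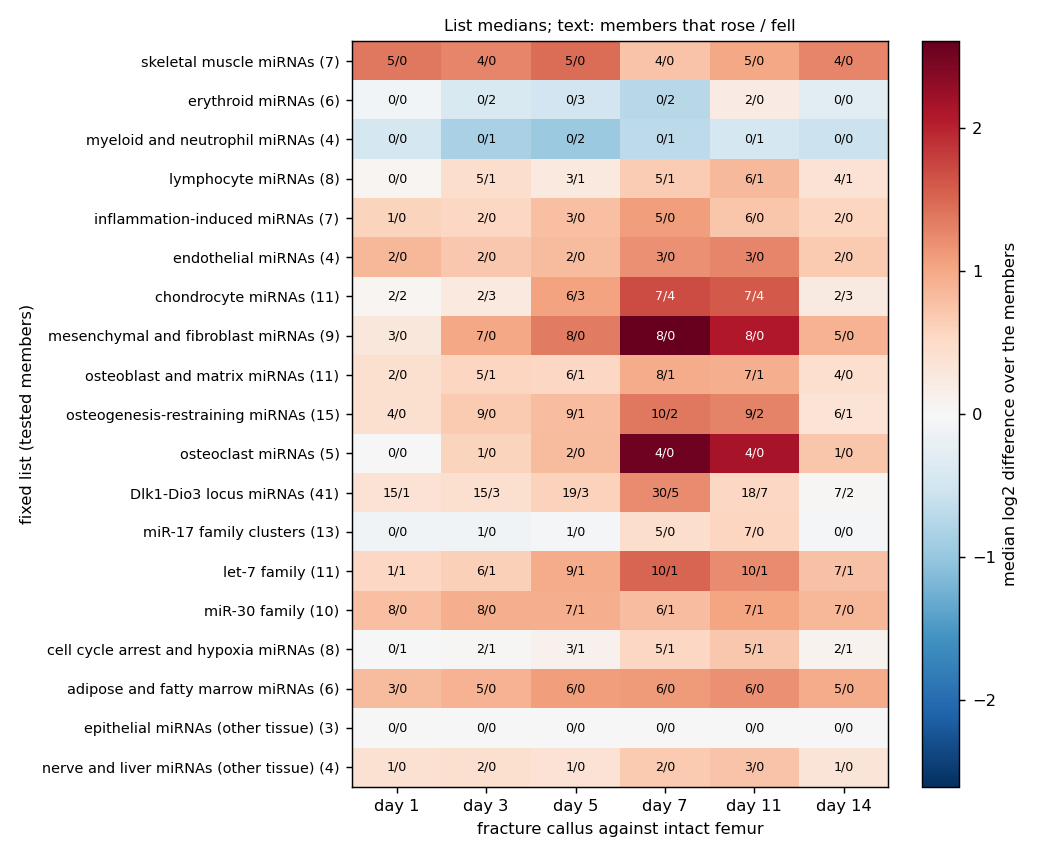
Median log2 difference from intact femur over the tested members of each fixed list (number in brackets) by day, with the numbers of members that rose and fell in each cell. The mesenchymal and fibroblast list has its highest median on day 7, 2.61, and medians that change sign without scaling or with spike-in scaling on day 7 include those of the skeletal muscle list (−0.38 and −0.14) and the miR-17 family clusters (−0.68 and −0.43).

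On day 11, 483 miRNAs differed from intact bone, 197 higher and 286 lower. Again miR-335-5p led the rises (16.9-fold, 4.08 ± 0.45, adjusted p = 4.01e-06), before miR-503-5p (11.1-fold, 3.47 ± 0.55), miR-455-3p (at least 8.90-fold, from intact arrays at the floor), miR-3968 (8.53-fold, 3.09 ± 0.37), and miR-140-5p (8.16-fold, 3.03 ± 0.49). The remaining rises were miR-140-3p (2.74 ± 0.43), miR-6366 (2.65 ± 0.29), miR-210-3p (2.57 ± 0.36), miR-214-3p (2.56 ± 0.40) and miR-152-3p (2.52 ± 0.35). The largest falls were miR-714 (−3.36 ± 0.45), miR-1931 (7.98-fold lower), miR-5128 (−2.99 ± 0.61), and miR-6956-5p (−2.88 ± 0.40). Then came miR-7040-5p (−2.78), miR-6392-3p (−2.78), miR-7684-3p (−2.75, well above background on 2 of 3 day 11 arrays), miR-3473e (−2.71), miR-7211-3p (−2.68) and miR-6961-5p (−2.64).

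Of the mesenchymal and fibroblast miRNAs 8 of 9 rose on day 11 (9 adjusted over the list alone; median 2.09) and of the osteoclast miRNAs 4 of 5 (4 adjusted over the list alone; median 2.16). Of the chondrocyte miRNAs 7 of 11 rose and 4 fell (7 and 4 adjusted over the list alone), with a median of 1.59 that was −0.26 with spike-in scaling. The miR-17 family clusters held 7 rises among 13 (7 adjusted over the list alone), such as miR-19b-3p (1.10 ± 0.18), with a median of 0.56 that was −0.58 without scaling and −1.28 with spike-in scaling. The lymphocyte miRNAs held 6 rises and 1 fall among 8 (6 and 1 adjusted over the list alone), led by miR-181b-5p (2.35 ± 0.27), with a median of 0.85 that was −0.30 without scaling and −1.05 with spike-in scaling. The Dlk1-Dio3 locus miRNAs held 18 rises and 7 falls among 41 (18 and 7 adjusted over the list alone; median 0.53, and just under 0 with spike-in scaling). In the erythroid miRNAs 2 of 6 rose, both miR-486 forms (0 adjusted over the list alone), while miR-144-3p was at 1.02 ± 0.78 and did not pass. The erythroid median of 0.22 was −0.76 without scaling and −1.43 with spike-in scaling. No list passed camera with an estimated correlation, the smallest adjusted p being 0.297.

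The day 11 split was 49 higher and 383 lower without scaling (shift −0.87) and 10 and 436 with spike-in scaling (shift −0.98). It was 211 and 205 by the 75th percentile over all probes, 214 and 214 by the median of detected probes, and 160 and 130 among the 347 miRNAs above background on all arrays. The rises of miR-140-3p, miR-210-3p, miR-214-3p and miR-152-3p did not pass with spike-in scaling. Days 11 and 14 lay on a slide of their own, so their differences from the other groups and the slide cannot be told apart. The labelling spike-in was 0.79 higher on that slide than on the others on the log2 scale. This offset lowers the values of days 11 and 14 against the other groups whenever spike-in scaling is used.

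On day 14, 192 miRNAs differed from intact bone, 88 higher and 104 lower. At the top were miR-335-5p (4.54-fold, 2.18 ± 0.45, adjusted p = 0.00234) and the muscle miRNAs miR-206-3p (3.56-fold, 1.83 ± 0.34) and miR-133a-5p (2.81-fold, 1.49 ± 0.29). The others were miR-378d (1.49 ± 0.22), miR-193b-3p (1.48 ± 0.22), miR-3968 (1.47 ± 0.37), miR-378a-3p (1.43 ± 0.22), miR-378a-5p (1.38 ± 0.27), miR-378b (1.37 ± 0.21) and miR-365-3p (1.36 ± 0.29). The largest falls were miR-1187 (−1.57 ± 0.36), miR-3082-5p (−1.45 ± 0.40), and miR-574-5p (−1.43 ± 0.32). Then came miR-669n (−1.25), miR-466i-5p (−1.24), miR-7089-5p (−1.06, well above background on 2 of 3 day 14 arrays), miR-1945 (−1.05), miR-211-3p (−1.01), miR-1247-3p (−0.95) and miR-7068-5p (−0.91).

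Of the skeletal muscle miRNAs 4 of 7 rose on day 14 (5 adjusted over the list alone; median 1.28), and of the adipose and fatty marrow miRNAs 5 of 6 (5 adjusted over the list alone), with a median of 0.96 that was −0.22 with spike-in scaling. The miR-30 family held 7 rises among 10 (7 adjusted over the list alone; median 0.86, and −0.24 with spike-in scaling) and the let-7 family 7 rises and 1 fall among 11 (8 and 1 adjusted over the list alone; median 0.77, and −0.34 with spike-in scaling). The mesenchymal and fibroblast miRNAs held 5 rises among 9 (7 adjusted over the list alone; median 0.90, and −0.23 with spike-in scaling). The chondrocyte miRNAs held 2 rises and 3 falls among 11 (2 and 3 adjusted over the list alone; median 0.24, and −0.28 with spike-in scaling) and the Dlk1-Dio3 locus miRNAs 7 rises and 2 falls among 41 (6 and 2 adjusted over the list alone; median 0.03, and −0.03 with spike-in scaling). Both miR-140 arms were at values that did not pass, miR-140-5p at 0.84 ± 0.49 and miR-140-3p at 0.91 ± 0.43. No list passed camera with an estimated correlation, the smallest adjusted p being 0.288.

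The day 14 split was 4 higher and 332 lower without scaling (shift −0.71), 1 and 414 with spike-in scaling (shift −0.87) and 114 and 61 in the authors' deposited table. The higher ones also outnumbered the lower with the software's sum per miRNA (120 and 74), among the 347 miRNAs above background on all arrays (95 and 27), by the 75th percentile over all probes (83 and 72) and at a 2-fold limit (46 and 8). Of the 10 largest rises 3 passed without scaling and 1, miR-335-5p, with spike-in scaling. The count was 105 without day 14 replicate 3 and 122 without intact replicate 3. Of the 10 largest falls 5, miR-1945, miR-211-3p, miR-3082-5p, miR-466i-5p and miR-7068-5p, did not pass without at least 1 array.

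The steps between sampled days asked when levels moved. Between days 1 and 3, limma called 0 of 663 miRNAs, with 69 at an unadjusted p under 0.05, and between days 3 and 5 it called 0, with 27. With the software's sum per miRNA the counts were 2 and 1, and in the authors' deposited table they were 1 and 0. The count for days 1 and 3 was 1 without day 1 replicate 2, day 3 replicate 2 or day 3 replicate 3, and every other setting gave 0 for both steps. Deviations of arrays with the same number correlated at 0.283 to 0.700 in the first of these steps and 0.168 to 0.535 in the second. The labels name no shared animal, so what arrays with the same number share is not known. The fit is unpaired, and none matched the arrays of these days alone by number, so changes within such matched arrays may be missed.

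Between days 5 and 7, 93 miRNAs rose and 189 fell. The largest rises were miR-503-5p (7.86-fold, 2.98 ± 0.55, adjusted p = 0.000517), miR-140-5p (6.06-fold, 2.60 ± 0.49) and miR-455-5p (5.05-fold, 2.34 ± 0.39, well above background on 2 of 3 day 5 arrays). Falling most were miR-5128 (−2.95 ± 0.61), miR-714 (−2.74 ± 0.45) and miR-6392-3p (−2.57 ± 0.61). The split was 161 higher and 163 lower after quantile normalization, 188 and 121 by the 75th percentile over all probes, 194 and 120 by the median of detected probes. It was 188 and 216 in the authors' deposited table, 26 and 147 without scaling, and 28 and 209 with spike-in scaling. With slide as a block 211 passed, resting on the 1 day 5 array on the slide of day 7. Without day 5 replicate 2 the differences were larger, at 3.88 for miR-503-5p, 3.39 for miR-140-5p, 2.98 for miR-455-5p and −3.70 for miR-5128.

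Between days 7 and 11, 9 miRNAs rose and 19 fell. The largest rises were miR-6402 (2.17-fold, 1.12 ± 0.16, adjusted p = 0.00115, well above background on 2 of 3 day 7 arrays), miR-1892 (0.73 ± 0.19) and miR-6898-5p (0.73 ± 0.17). The largest falls were miR-376b-3p of the Dlk1-Dio3 locus (−1.39 ± 0.31), miR-675-3p from H19 (−1.07 ± 0.26) and miR-541-5p, at least 2.79-fold lower and not well above background on day 11. Each of these but miR-6402 missed the threshold without at least 1 array, and miR-6402 missed it without scaling and with spike-in scaling. The count was 14 without day 7 replicate 1, 11 without day 7 replicate 2, 17 without day 11 replicate 1 and 9 without day 11 replicate 3. The split was 2 higher and 55 lower by the 75th percentile over all probes, 33 and 11 in the authors' deposited table, 66 and 13 with the software's sum per miRNA and 32 and 24 with slide as a random block. It was 0 and 0 without scaling, and 0 and 185 with spike-in scaling, where miR-1892 (−0.26) and miR-6898-5p (−0.27) turned.

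Between days 11 and 14, 189 miRNAs rose and 123 fell. The largest rises were miR-714 (4.91-fold, 2.30 ± 0.45), miR-5128 (4.76-fold, 2.25 ± 0.61) and miR-7040-5p (4.69-fold, 2.23 ± 0.49, adjusted p = 0.00293). Falling most were miR-503-5p (−2.67 ± 0.55), miR-144-3p (−2.38 ± 0.78) and miR-140-5p (−2.18 ± 0.49). These groups shared a slide, and 314 miRNAs passed on its arrays alone, which are the arrays of these groups and so no separate check of the slide. The split was 132 higher and 162 lower by the 75th percentile over all probes, 135 and 183 by the median of detected probes, 166 and 25 without scaling and 160 and 9 with spike-in scaling. The fall of miR-144-3p did not pass without scaling, with spike-in scaling or without day 11 replicate 1, day 14 replicate 1 or day 14 replicate 2.

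Of the 114 tests of a list on a day, 0 passed with camera at an estimated correlation, 61 at the preset correlation of 0.01, all upward, and 81 with fry, 73 upward and 8 downward. The fry test asks whether members move in 1 direction on balance and compares no list with other miRNAs. None of the 61 calls at the preset correlation held with an estimated correlation (0 of 61). The power of camera for correlated lists was not measured, so the 0 calls do not show that no list moved. The smallest p among the 61 was that of the Dlk1-Dio3 locus miRNAs on day 7 (adjusted p = 7.74e-06 at the preset correlation, and adjusted p = 0.299 with an estimated correlation).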

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

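The tests of scaling, labelling, the day 7 slide and muscle RNA below were chosen after the results were seen. Those of array brightness, the early-day slide and the splits were written before their values were computed.

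The rises and falls on day 7, such as miR-503-5p (4.89) and miR-5128 (−4.90), came with a 75th percentile 1.15 lower on the log2 scale than in intact bone. Scaling could produce part of the 205 rises: 145 of them (70.7%) kept a higher day 7 mean without scaling, a share between the bounds set for either reading, so the test leaves this undecided. Labelling efficiency predicted a labelling spike-in at least 0.8 lower on day 7. The spike-in differed by −0.25 (SE 0.19), which speaks against labelling as the whole cause. The slide predicted fewer calls on the slide of both groups, where there were 498. As that slide holds every array of both groups, the count is no separate check, and no difference between slides enters the comparison. Array brightness predicted a within-group correlation with the falls numbered 1000 or higher, and over 21 arrays it was 0.218 (permutation p = 0.413), with 0.0172, 0.819 and 0.901 within the 3 slides. Brightness therefore remains possible.

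Skeletal muscle miRNAs may have risen because the callus samples hold more muscle RNA, in which case those that rose would rise alike. On day 1 the largest and smallest of 5 rises, miR-133a-5p and miR-206-3p, differed by 0.35 (SE 0.33), which is what more muscle RNA needs, though it also allows regulation of all 5. On day 7 miR-206-3p rose by 1.94 (SE 0.34) more than miR-133a-3p, which argues against more muscle RNA of unchanged composition as the only cause of its rise. What else raised miR-206-3p was not analysed here.

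Changes on days 1, 3 and 5 could come from the slide, since only day 5 joins the slides of these days and of intact bone. Over the 124 day 1 calls, turned to the sign of the call, the day 5 arrays on slide 1 exceeded the day 5 array on slide 2 by a median of −0.0069, against a median day 1 size of 0.73. The bound written beforehand reads this as speaking against the slide, but it rests on 1 array of slide 2, so the question stays open.

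Among 100 regroupings of all arrays, with the real grouping counted, 1 gave as many differing miRNAs as the real 499 (next 222) and 1 as many changed on all 6 days as the real 100 (next 9). For the lists all 100 reached the real 0 calls (highest 5), as any grouping must, so that comparison says nothing. In fits of 2 groups, the real split alone, 1 of 10, reached its count for day 1 (137), day 3 (88), day 5 (282), day 7 (498), day 11 (492) and day 14 (281) against intact bone. The same held for day 7 against day 5 (162), day 11 against day 7 (2, next 1) and day 14 against day 11 (314), 1 of 10 each. For day 3 against day 1 and day 5 against day 3, with 0 calls, 10 of 10 reached the count, as any split must, which says nothing. As 10 splits allow no share under 10%, these cannot rule chance out.

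Several miRNAs passed in opposite directions against intact bone on different days. The days compared below lay on different slides, so a difference between slides could enter each value. From day 3 to day 7 the difference was −2.79 for miR-7005-5p (1.17 to −1.62). It was −2.63 for miR-7219-5p. It was −2.02 for miR-494-3p of the Dlk1-Dio3 locus. It was −1.84 for miR-6354. For miR-6351 it was −1.18, with both signs kept in 5 of 6 other scalings. From day 3 to day 11 it was −2.03 for miR-6378. It was −1.80 for miR-7042-5p. For miR-8117 it was −1.59. From day 7 to day 11 miR-6402 differed by 1.12, with both signs kept in 4 of 6 other scalings. From day 1 to day 7 miR-3085-5p differed by −0.37, with no day 7 array well above background and both signs kept in 5 of 6 other scalings. The labelling spike-in was 0.60 higher on the arrays of days 11 and 14 than in intact bone (exact permutation p = 0.0119, the smallest possible for these arrays). Those arrays make up slide 3, and each exceeded every array of slides 1 and 2 (mean difference 0.79, exact permutation p = 1.84e-05, again the smallest possible). Both permutations treat the arrays of a slide as independent, so neither p measures the spread between slides. Slide and day cannot be told apart here, and the offset enters the spike-in-scaled values of days 11 and 14.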

How the results depend on the processing

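The settings of no scaling, spike-in scaling, the lowest floor, single slides and numbers under 1000 were chosen after the results were seen. The counts depend on a 2-fold limit, on scaling, on requiring signal above background on every array and, for days 1, 3 and 5, on the slide. Of 393 count values 314 stayed within 1.5 times the value reported. Of 3149 values of named miRNAs 2879 kept their call, 268 lost it and 2 reversed: with spike-in scaling miR-1892 (−0.26) and miR-6898-5p (−0.27) on day 11 against day 7. Of 4498 list tests 1 reversed, the epithelial list on day 7 with fry (adjusted p = 0.0170, against 0.551 to 0.998 in its other settings).

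Day 11 against day 7 had 57 calls with the 75th percentile over all probes, 56 with the median of detected probes and 56 with slide as a random block. The normexp signal gave 435 and the lowest floor 428 for day 7 against day 5. The software's sum gave 2 for day 3 against day 1, 1 for day 5 against day 3 and 79 for day 11 against day 7. The authors' table gave 1 for day 3 against day 1 and 44 for day 11 against day 7. Without a filter day 3 had 191, day 11 against day 7 had 12 and the lists 2.

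With only the 347 miRNAs above background on all arrays, against 663 tested, days 1, 3, 5, 7, 11 and 14 had 68, 191, 228, 297, 290 and 122 calls. Higher ones numbered 60, 129, 134, 156, 160 and 95 of these, and lower ones 8, 62, 94, 141, 130 and 27. On days 3, 5, 7, 11 and 14 the excess of falls thus turned. This filter leaves out miRNAs that fell below background on any array, as well as those that rose from it. Of the day 7 calls with a group at the floor 97 were lower and 46 higher. The turn may therefore come from the filter itself. Day 7 against day 5 had 185, day 11 against day 7 had 0 and day 14 against day 11 had 197; 57 passed on all 6 days and 296 in the F-test. Without scaling day 1 had 63 and day 14 had 336. Day 7 against day 5 had 173, day 11 against day 7 had 0, day 14 against day 11 had 191, and 5 passed on all 6 days. With spike-in scaling day 3 had 183, day 14 had 415, day 11 against day 7 had 185 and day 14 against day 11 had 169, and 8 passed on all 6 days.

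With slide as a fixed block days 1, 3 and 5 had 48, 56 and 146. Fits of 2 groups gave 88 for day 3, 162 for day 7 against day 5, 2 for day 11 against day 7 and 48 on all 6 days. At least 2-fold, the days had 41, 99, 145, 317, 298 and 54, the last 3 steps 153, 4 and 141, and all 6 days 21. Numbered under 1000, days 3, 5, 7, 11 and 14 had 145, 179, 245, 233 and 117, day 7 against day 5 had 122, day 14 against day 11 had 144 and the F-test 247. The lists had 61 calls at the preset correlation and 81 with fry. With the replicate number as a block day 1 had 151, day 3 had 317, day 11 against day 7 had 34 and all 6 days 122.

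With 1 array left out, day 1 had 72 to 146 calls (72 without day 1 replicate 2, 76 without intact replicate 3). Day 3 had 162 to 361 (162 without day 3 replicate 2, 193 without intact replicate 1, 190 without intact replicate 3). Day 5 had 228 to 392 (228 without day 5 replicate 2). Day 14 had 105 to 204 (105 without day 14 replicate 3, 122 without intact replicate 3). Day 3 against day 1 had 0 to 1 (1 without day 1 replicate 2, day 3 replicate 2 or day 3 replicate 3). Day 11 against day 7 had 9 to 27 (14 without day 7 replicate 1, 11 without day 7 replicate 2, 17 without day 11 replicate 1, 9 without day 11 replicate 3). All 6 days had 59 to 138 (59 without intact replicate 3, 62 without day 1 replicate 2). Day 7 had 472 to 494, day 11 had 454 to 474 and the F-test 467 to 510.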

Other observations

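The groupings in this part were chosen after the results were seen, and none was tested for enrichment unless a p is given. Of the miRNAs named miR-466, miR-467 or miR-669, grouped by name alone as genome positions were not analysed here, 15 were tested. On day 7 12 rose and 2 fell, with a median of 0.85 that was 0.21 without scaling, and on day 11 11 rose and 2 fell, with a median of 1.34 that was 0 with spike-in scaling. The rises included miR-466f-3p (2.24 on day 11). The 2 that fell, miR-466i-5p and miR-669n, also fell on days 1 and 14.

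The arms of a hairpin were called in the same and in opposite directions. Of 85 hairpins with both arms tested, 43 had both arms called on day 7, 27 in the same direction and 16 in opposite directions, and on day 11 the counts were 22 and 18. Whether these splits differ from chance was not tested. In miR-193b the 3p arm rose on day 7 (1.70 for miR-193b-3p) while miR-193b-5p was at least 2.62-fold lower, and the arms of miR-365 divided likewise.

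High-numbered miRNAs, which were described later, behaved unlike the others. Of 333 tested miRNAs numbered 1000 or higher 16 rose and 236 fell on day 7, and of 330 with lower numbers 189 rose and 57 fell (Fisher's exact p = 2.80e-64, with miRNAs that are not independent replicates). Between days 11 and 14, 156 of the high-numbered miRNAs rose and 10 fell.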
